A study of Drosophila melanogaster with 12 samples.

How the data were processed

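The series holds 12 RNA-seq libraries of fly heads: 8 labelled cabut RNAi (Tim-gal4 with UAS-cbt RNAi), 2 at each of 0, 25, 50 and 100 percent sucrose, and 4 controls carrying the UAS transgene without the driver, 1 at each concentration, all at 18 h. Per the labels' protocols, RNA was fragmented before poly(A) selection, so reads come from 3' ends. Bowtie, TopHat and build dm3 are named in the submitters' processing notes, without versions; the counting tool, the use of strand and the normalization method are not given in the sources used here. Antisense and overlapping genes could therefore not be told apart.

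The deposited table holds 21081 transcript rows with 1 column per library. Its unit is a signal that the authors deposited as normalized values: every value was a whole multiple of 1 step per library (100 percent of values within a tolerance of 0.01), so the reads behind it were recovered by division. Per library 511442 to 1859025 reads were recovered with 1 row per gene. Transcript rows were joined to genes by the CG or CR number of the FlyBase transcript. Of 14010 such numbers, 13635 matched a symbol in the RefSeq gene table given for names, which left 13744 genes. A gene was represented by its transcript row with the highest mean; 12526 genes had 1 distinct row and 1218 had 2 or more. For 99 genes with at least 100 reads, the reads in every library equalled those of another gene, and none of these is named. Starts in the table count from 0, and printed coordinates count from 1, in build dm3.

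The design had assumed normalized values, and the unit fitted. Each gene was tested on log2(value + 1) with limma 3.58.1 (intensity trend; R 4.3.3), for the 6549 genes with a mean of at least 10 over the 12 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Labels and sucrose were fitted together over 12 libraries with concentration as a factor; the dose trend used the 9 libraries with sucrose; the response within libraries labelled cabut RNAi used those 8; the difference of responses, the response within controls and the differences at each concentration came from 8 group means. With 1 control library per concentration, the control's spread is assumed to be that of the other groups. Replicates of a group differed by more than counting noise (chi-square over its degrees of freedom between 2.89 and 6.24), so none was treated as a repeat.

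The 22 gene lists were fixed before the data were examined: sugar sensing and cabut; glycolysis and gluconeogenesis; pentose phosphate, glycogen, trehalose and polyol; lipogenesis; lipolysis and fatty acid oxidation; FOXO, TOR and starvation; circadian; carbohydrate digestion; insulin-like and feeding peptides; antimicrobial and immune; heat shock; detoxification; ribosome biogenesis; cytosolic ribosomal proteins; mitochondrially encoded; markers of photoreceptors, neurons, glia, fat body and yolk, muscle and hemocytes; and male dosage RNAs. The 21 with at least 3 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Genes were named by a rule also fixed before: cbt; the 12 largest changes in each direction among calls with a mean of at least 50 for labels and for sucrose; 6 in each direction for other comparisons; and up to 4 called members of each list, or the member with the smallest p.

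Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, median-of-ratios and quantile scaling, limma without the trend and with robust estimation, leaving out each library, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a linear dose, an F test over the 4 concentrations, and no concentration term. Summing the distinct transcript rows of a gene, and the list tests without the control library at 100 percent sucrose, were added after seeing the data.

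The tests were tried on simulated negative binomial reads with the real means and library sizes, 200 of 6549 genes being changed. Each simulated gene took the spread that edgeR fitted as a trend over abundance, so genes of like abundance varied alike. Real genes can depart from that trend, so the shares below may be too favourable. For labels limma recovered 46.3 percent of genes changed 1.5-fold, 80.6 percent of those changed 2-fold and 97 percent of those changed 4-fold, and 7.5 percent of its calls were unchanged genes. For sucrose the shares were 38.8, 82.1 and 98.5 percent, with 7 percent unchanged. For the difference of responses they were 4.5, 20.9 and 75.8 percent, with 25.6 percent unchanged, and the response in controls and the difference at 0 percent sucrose had 27.6 and 25.8 percent unchanged. Calls that rest on single control libraries are thus less reliable than the adjusted p states. A simulated list of 20 genes moved by 0.5 on the log2 scale was recovered, and 0 of 100 unmoved lists were called. The simulated genes were drawn independently, so this could not test the preset correlation. For labels the estimated correlation was 0.583 in the ribosomal protein list and 0.68 in the muscle list. The values of 1 gene are not reported here.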

Results

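Poly(A) 3' RNA-seq was measured in heads of Drosophila melanogaster (Canton-S background) after 18 h on 0, 25, 50 or 100 percent sucrose, the percentages being those of the labels. At each concentration there were 2 libraries labelled cabut RNAi, from flies in which the driver Tim-gal4 acts on a UAS-cbt RNAi transgene, and 1 control library from flies that carried the UAS transgene without the driver. The 12 libraries held between 511442 and 1859025 reads when 1 transcript row was kept per gene. The shallowest was the control library at 100 percent sucrose. Values are reads scaled by 1 factor per library and are called normalized reads here. Errors on log2 fold changes are standard errors (SE), and groups are given as mean ± SD. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Where labels and sucrose were fitted together, that spread also held any difference of the sucrose response between labels. Because each control group held 1 library, a difference at a single concentration had no replicate on the control side.

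The first question was whether the targeted RNA, cbt (cabut, CG4427, transcript CG4427-RB, chromosome 2L, 476437 to 479046 in build dm3), a zinc-finger transcription factor gene, was lower in the libraries labelled cabut RNAi. It was not lower. The 2 libraries labelled cabut RNAi held 114.5 ± 17.4 normalized reads of cbt at 0 percent sucrose (SD, n = 2) and the 6 with sucrose held 163 ± 28.4 (SD, n = 6). There were 93.5 in the control library at 0 percent and 122 ± 21 in the 3 control libraries with sucrose (SD, n = 3). The mean of the libraries labelled cabut RNAi was above the control value at all 4 concentrations. The fitted log2 fold change was 0.38 ± 0.13 (SE), with a limma adjusted p of 0.0539. In all 24 alternatives the value was above 0, and in 9 it passed the threshold as higher in the libraries labelled cabut RNAi, with adjusted p down to 0.0196 (without the second library labelled cabut RNAi at 25 percent sucrose). Others of the 9 were robust limma (0.031) and the fit without the control library at 25 percent (0.0275). Without the control library at 100 percent sucrose it was 0.19 (adjusted p = 0.363). Reads from the RNAi transgene itself could not be told from those of the gene. The phrase "libraries labelled cabut RNAi" is therefore used throughout, and every direction between genotypes below is a direction between labels, not evidence of lower cbt RNA. Other genes separated the labels: w, the white eye-colour transporter gene often carried by transgenes, held 32.7 ± 7.10 normalized reads in the libraries labelled cabut RNAi (SD, n = 8) and 10.7 ± 5.88 in the controls (SD, n = 4).

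**Figure D1:**
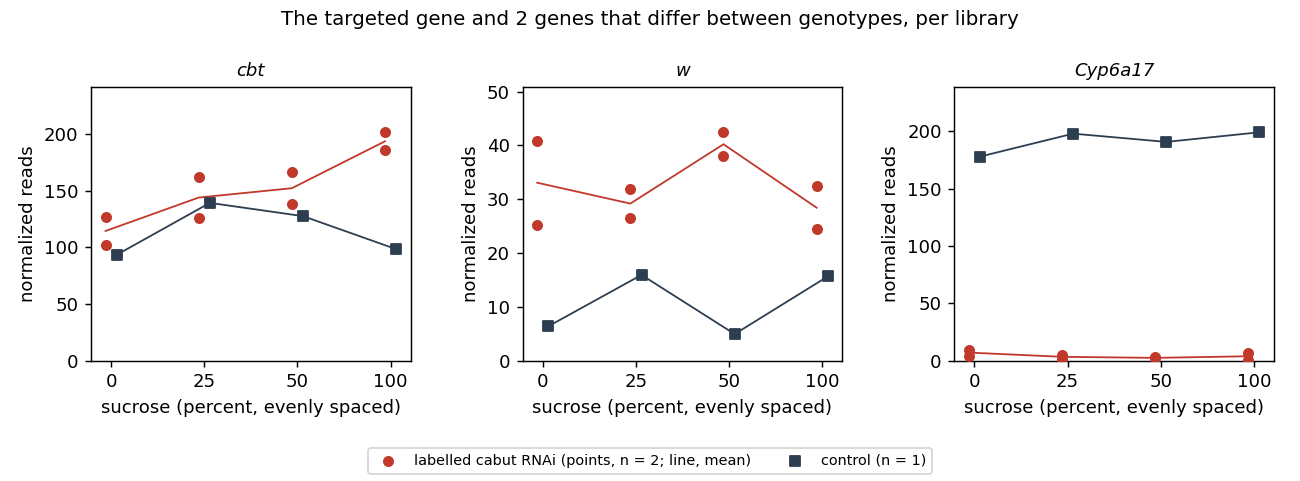
Normalized reads (vertical axis, starting at 0) of cbt, w and Cyp6a17 against sucrose concentration (percent, evenly spaced); red points are the 2 libraries labelled cabut RNAi per concentration with a line through their mean, and dark squares are the single control library. The mean cbt value of the libraries labelled cabut RNAi lies above the control value at each concentration, although 1 of the 8 lies below it (125.8 against 139.3 at 25 percent), while Cyp6a17 lies at 191.5 ± 9.73 in the controls (SD, n = 4) and 4.25 ± 2.98 in the libraries labelled cabut RNAi (SD, n = 8).

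The comparison of the libraries labelled cabut RNAi with the controls over all concentrations asked which head transcripts differ between the genotypes. Cytochrome P450 genes were among those with large differences. Cyp6a17 was 42.3-fold lower in the libraries labelled cabut RNAi (log2 fold change -5.40 ± 0.34, n = 8 and 4). Cyp4e3 was 25.1-fold higher (954 ± 130 against 50.7 ± 53.4 normalized reads), Cyp4p1 7.91-fold, Cyp6a8 5.93-fold and Cyp6a23 4.98-fold higher. The Turandot genes TotC (16.3-fold) and TotA (9.89-fold), which encode secreted stress peptides, and the antimicrobial peptide gene Mtk (5.78-fold) were lower. Of 6549 genes tested, 444 were higher and 571 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 955 had the same sign at all 4 concentrations, a count raised by choosing the genes on their difference over those same concentrations. With quantile normalization 479 were higher and 458 lower. Without the control library at 100 percent sucrose, 290 genes were higher and 433 lower, and 664 of the 1015 calls remained.

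Further genes at the top of this list were CG3348, 53.8-fold higher in the libraries labelled cabut RNAi (log2 fold change 5.75 ± 0.25), with CG32444, CG3609, CG12896 and CG9377 between 4.94- and 5.81-fold higher. Lower were the cuticular protein gene Cpr72Ec (11.5-fold), the odorant-binding protein gene Obp99b (4.59-fold), the serpin gene Spn88Eb (4.28-fold), lncRNA:CR32368 (8.91-fold), CG16743 (3.90-fold) and se (3.22-fold), which acts in eye pigment synthesis. Of the 24 genes named by the rule, 20 kept their call when each library was left out in turn. The exceptions were the adult cuticle gene Acp1 (log2 fold change 3.52 ± 0.90), CG31904 (3.44 ± 0.91), TotM (-2.22 ± 0.53) and Cyp4g1 (-2.79 ± 0.70). Without the control library at 100 percent sucrose these were 2.98 (adjusted p = 0.126), 3.14 (0.115), -1.61 (0.119) and -1.43 (0.0759). Acp1 spread widely between libraries labelled cabut RNAi (370 ± 450 normalized reads, SD, n = 8), and Acp1 and CG31904 also lost the call without the control library at 50 percent (adjusted p = 0.0689 and 0.0928), and CG31904 without that at 25 percent (0.0677). CG7214 was 41.4-fold higher, with an SE of 0.79 on the log2 scale. Cyp6a17 and Cyp6a23 are neighbouring, closely related genes, so reads may have been divided between them.

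Among the lists fixed before the data were examined, the cytosolic ribosomal protein genes moved most uniformly. In the libraries labelled cabut RNAi, 79 of 82 were lower and none higher (median log2 fold change -0.54; adjusted over the list alone, 81 lower). With quantile normalization 26 were lower and 2 higher, with a median of -0.11. RpS21 (-0.87 ± 0.08) and RpL11 (-0.87 ± 0.09) led the list, followed by RpLP1 (-0.83 ± 0.08) and RpS18 (-0.76 ± 0.07). These genes took 20.6 to 22.8 percent of the reads in libraries labelled cabut RNAi and 26.8 to 28.8 percent in controls. The set test (limma camera with a preset correlation) gave an adjusted p of 6.95e-62, and adjusted p = 0.236 with an estimated correlation. The ribosome biogenesis list had 2 of 12 lower, nop5 (-1.02 ± 0.19) and Myc (-0.70 ± 0.15), with 3 lower adjusted over the list alone (camera adjusted p = 0.0223; adjusted p = 0.236 with an estimated correlation).

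**Figure D2:**
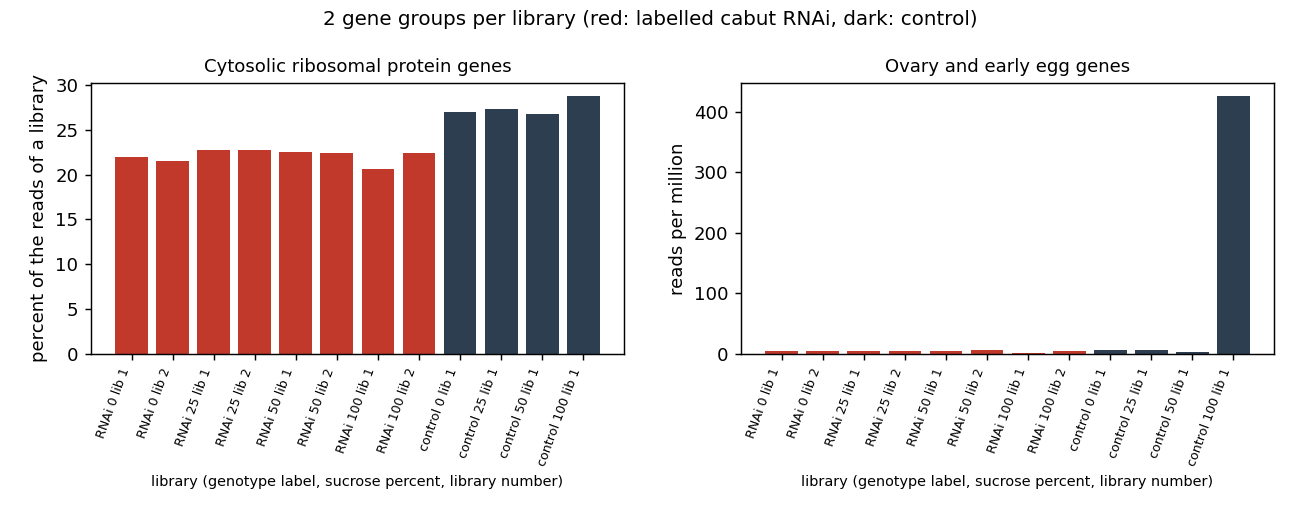
Left, percent of a library's reads in the 82 cytosolic ribosomal protein genes; right, RPM (reads scaled to a common library total) of 16 ovary and early egg genes; each bar is 1 of the 12 libraries, red for those labelled cabut RNAi and dark for controls. Ribosomal protein genes take a larger share in the 4 controls. These shares are of recovered reads, without quantile normalization, which moved the median log2 fold change of these genes between labels from -0.54 to -0.11. The ovary genes reach 426 RPM in the control library at 100 percent sucrose against at most 6 RPM in the other 11.

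Carbohydrate genes differed in both directions. In glycolysis and gluconeogenesis, 5 of 15 were higher and 1 lower in the libraries labelled cabut RNAi (6 and 1 adjusted over the list alone). The phosphoenolpyruvate carboxykinase genes Pepck2 (2.53 ± 0.40) and Pepck1 (1.08 ± 0.20), the aldolase gene Ald1 (0.55 ± 0.07), fbp and Gapdh1 were higher. The sucrose responses of both Pepck genes differed between labels (below). At 0 percent sucrose Pepck1 was not higher, with 1608 and 1511 normalized reads against 1853 in the control. With sucrose it held 796.7 to 1290 against 356.8 to 382.7 in controls. The hexokinase gene Hex-C was lower (-0.56 ± 0.11). In the pentose phosphate, glycogen, trehalose and polyol list 6 of 14 were higher, among them Sodh2 (1.13 ± 0.17) and Glyp, glycogen phosphorylase (0.82 ± 0.10), while 1 was lower, Pgm1 (-0.56 ± 0.11), with 7 and 2 adjusted over the list alone. In the sugar sensing and cabut list 2 of 7 were higher, both Pepck genes, and bigmax was lower (-0.35 ± 0.11; lost in 9 of 12 fits that left out a library, adjusted p up to 0.164), with 5 higher and 1 lower adjusted over the list alone. Camera adjusted p-values of these lists were 0.0136, 0.00997 and 0.0197, and each was lost with an estimated correlation (adjusted p = 0.432, 0.365 and 0.365). With the control library at 100 percent sucrose left out, the camera adjusted p was 0.0865 for glycolysis and 0.093 for sugar sensing. In lipolysis and fatty acid oxidation 5 of 14 were lower and none higher, including CPT2 (-0.97 ± 0.14) and Arc42 (-0.93 ± 0.16), with 7 lower adjusted over the list alone (camera adjusted p = 0.00224; adjusted p = 0.236 with an estimated correlation).

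Of 12 detoxification genes, 6 were higher and Cyp6a17 was lower, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.00344; adjusted p = 0.365 with an estimated correlation). Of 16 antimicrobial and immune genes 5 were lower, with 8 adjusted over the list alone (camera adjusted p = 7.81e-04; adjusted p = 0.378 with an estimated correlation), and 3 without the control library at 100 percent sucrose. In the fat body and yolk list 5 of 9 were lower, among them the yolk protein genes Yp1 (-0.78 ± 0.14) and Yp3 (-0.88 ± 0.15). Lsp2 was higher (1.83 ± 0.30), with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.365 with an estimated correlation). Glial markers had 4 of 8 higher, led by nrv2 (0.74 ± 0.08) and the glutamate transporter gene Eaat1 (0.64 ± 0.09). There were 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0362; adjusted p = 0.239 with an estimated correlation; 0.0864 without the control library at 100 percent sucrose). Muscle had 3 of 7 higher (Prm 0.65 ± 0.17, Mhc 0.41 ± 0.12 and wupA 0.35 ± 0.11; 4 adjusted over the list alone), and none without the control library at 100 percent sucrose (camera adjusted p = 0.0136 with all libraries and 0.0968 without it; adjusted p = 0.462 with an estimated correlation).

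The remaining lists also held calls in the comparison of labels, in most of these lists in both directions. Over all genes 1015 of 6549 were called. None of these lists passed the camera test, which looks for a shift in 1 direction. The circadian list had 2 higher (to and vri) and 2 lower of 12, the neuropeptide gene Pdf being lower (-0.85 ± 0.12). The calls of to and vri were lost in 8 and 2 fits that left out a library (adjusted p up to 0.151 and 0.0728). Insulin-like and feeding peptides had 3 higher and 1 lower of 13, lipogenesis 1 higher and 2 lower of 10 (none without the control library at 100 percent sucrose), FOXO, TOR and starvation genes 2 and 2 of 13, and carbohydrate digestion 1 and 1 of 7. Photoreceptor markers had 3 higher and 3 lower of 17, with Rh5 the largest (0.73 ± 0.12), neurons 1 and 2 of 11, heat shock genes 1 and 1 of 7, and hemocytes 1 of 6 higher, Hml (0.62 ± 0.13). Mitochondrially encoded genes had 4 of 13 lower, and the 1 named with a reversed sign under quantile normalization was ATP6 (-0.31 ± 0.07 as deposited, 0.13 after it). Adjusted over the list alone, insulin-like and feeding peptides had 4 higher, photoreceptor markers 4 lower, and the other 8 tested lists of this paragraph had the same counts. Without the control library at 100 percent sucrose insulin-like and feeding peptides had 1 higher and 1 lower, FOXO, TOR and starvation genes 1 higher, heat shock genes none, and circadian genes 1 higher and 2 lower. For the neuron list the median was 0.05 and the mean -0.02. The male dosage list had no member among the genes tested.

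Sucrose against none, averaged over 25, 50 and 100 percent and both genotypes, asked which transcripts differ between flies with and without sucrose. If the food at 0 percent held no other nutrient, a response to sugar cannot be told apart from a response to feeding as such. Lipid-breakdown genes fell: the lipase-family gene CG5966 was 6.37-fold lower with sucrose (log2 fold change -2.67 ± 0.16), the secreted phospholipase gene GIIIspla2 4.90-fold, the triglyceride lipase gene bmm 2.53-fold and the medium-chain acyl-CoA dehydrogenase gene Mcad 2.46-fold. Shmt (serine hydroxymethyltransferase, 4.18-fold), the purine synthesis genes Gart (3.61-fold), CG11089 (2.47-fold) and Pfas (2.42-fold), Gnmt (3.02-fold), the amylase gene Amy-p (2.89-fold) and the galactokinase gene Galk (2.47-fold) fell as well, as did CG31075 (2.89-fold). The genes that rose were led by fit, a female-enriched fat body gene (4.96-fold, log2 fold change 2.31 ± 0.29), CG3348 (4.12-fold) and phu (3.51-fold). Next were Pisd, phosphatidylserine decarboxylase (2.48-fold), CG32425 (2.34-fold) and Phyhd1 (2.18-fold). Then came sug, the sugar-responsive transcription factor gene sugarbabe (2-fold in the fit over all 12 libraries), and the perilipin gene Lsd-1 (1.84-fold). In all, 44 genes were higher and 97 lower of 6549 (limma, adjusted p under 0.05).

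The log2 response of sug was 1.41 ± 0.14 in the libraries labelled cabut RNAi and 0.17 ± 0.20 in controls (limma adjusted p = 0.77 for the controls). The difference of the responses did not pass (adjusted p = 0.0816). CG10214 and CG8157 also rose (1.77- and 1.71-fold). Of the 24 genes named by the rule, 19 kept the call when each library was left out in turn. The others were sug, Phyhd1 and Obp56h, which lost it without either library labelled cabut RNAi at 0 percent sucrose, CG5773, which lost it without the first of those, and phu, which lost it in 8 of 12 such fits. The highest adjusted p was 0.0732 for sug, 0.0835 for Phyhd1, 0.143 for Obp56h, 0.148 for CG5773 and 0.248 for phu. Without the first library labelled cabut RNAi at 0 percent sucrose the comparison called 87 genes in place of 141, of which 80 were among the 141. For cbt the log2 fold change with sucrose was 0.45 ± 0.14, not past the threshold over all genes (adjusted p = 0.13) and past it adjusted over the list alone (0.00682).

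In the list of lipolysis and fatty acid oxidation genes, 7 of 14 fell with sucrose and none rose (10 adjusted over the list alone). These were bmm, Mcad (-1.30 ± 0.13), CG3902 (-1.05 ± 0.14), yip2 (-1.01 ± 0.10), Mtpalpha (-0.79 ± 0.13), Mtpbeta (-0.71 ± 0.10) and the carnitine palmitoyltransferase gene whd (-0.36 ± 0.09). Its camera adjusted p was 1.34e-16, and it was the 1 list of 21 past the threshold with an estimated correlation (adjusted p = 0.00826). In glycolysis and gluconeogenesis 3 of 15 fell, Pepck2 (-2.41 ± 0.43), Pepck1 (-1.13 ± 0.22) and Pgi (-0.34 ± 0.09). There were 6 adjusted over the list alone (camera adjusted p = 1.20e-04; adjusted p = 0.203 with an estimated correlation). The Pgi call was lost in 11 of 12 fits that left out a library, with adjusted p up to 0.433. Without the control library at 0 percent sucrose the Pepck2 value was -1.51. Carbohydrate digestion had 2 of 7 lower, Amy-p and Amy-d (-0.91 ± 0.16), near-identical copies between which reads may have been divided. The same 2 were lower adjusted over the list alone (camera adjusted p = 0.00567; adjusted p = 0.193 with an estimated correlation). Detoxification had 3 of 12 lower, Ugt35C1 (-0.98 ± 0.17), Cyp6a8 (-0.88 ± 0.21) and Cyp4e2 (-0.85 ± 0.11), with 6 adjusted over the list alone (camera adjusted p = 7.16e-08; adjusted p = 0.184 with an estimated correlation). The Cyp6a8 call was lost in 4 fits that left out a library (adjusted p up to 0.337).

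**Figure D3:**
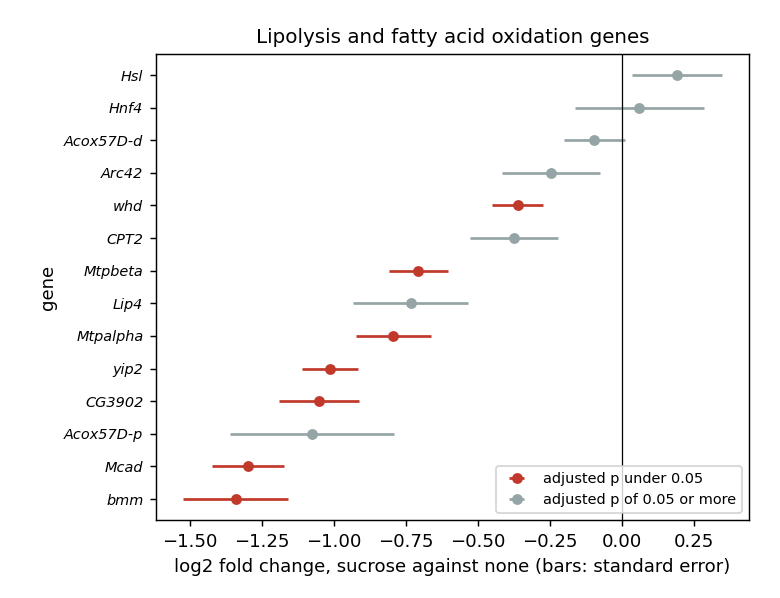
Log2 fold change with sucrose against none (horizontal axis) for the 14 tested genes of the lipolysis and fatty acid oxidation list (vertical axis); points are estimates over 12 libraries, bars their standard errors, and red marks an adjusted p under 0.05. The 7 red genes all lie below 0, from -0.36 for whd to -1.34 for bmm.

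In the sugar sensing and cabut list, sug (1.0 ± 0.19) and daw, an activin-like ligand gene (0.66 ± 0.15), rose and both Pepck genes fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.745). In the pentose phosphate, glycogen, trehalose and polyol list Sodh1 (-1.11 ± 0.16) and Pgls (-0.69 ± 0.14) fell (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.114). In lipogenesis the fatty acid synthase gene FASN1 rose (0.60 ± 0.14; 2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.163). The daw and FASN1 calls were each lost in 3 fits that left out a library at 0 percent (adjusted p up to 0.0933 and 0.168), Pgls in 1 (0.111) and Pepck2 in 1 (0.0854). In the fat body and yolk list fit was the 1 member of 9 past the threshold, with 3 higher adjusted over the list alone (camera adjusted p = 1.20e-04; adjusted p = 0.193 with an estimated correlation). No member of the other 13 tested lists passed over all genes. Of these, camera called 6 upward: ribosomal protein genes (median log2 fold change 0.08, adjusted p = 4.98e-06; adjusted p = 0.514 with an estimated correlation), muscle (0.19, 0.00424; 0.349), insulin-like and feeding peptides (0.18, 0.0248; 0.193), mitochondrially encoded (0.16, 0.0248; 0.514), photoreceptor (0.10, 0.0262; 0.203) and glia (0.15, 0.0474; 0.193). FOXO, TOR and starvation, circadian, antimicrobial, heat shock, ribosome biogenesis, neuron and hemocyte genes did not pass (camera adjusted p from 0.0947 to 0.745). Adjusted over the list alone, FOXO genes had 2 lower, feeding peptides and ribosome biogenesis 1 higher and 1 lower each, glia and muscle 1 higher each, and the other 8 lists none. Median and mean differed in sign for the sugar sensing (0.04 and -0.22), FOXO (0.003 and -0.101), circadian (-0.008 and 0.039), heat shock (-0.021 and 0.014) and hemocyte (-0.037 and 0.017) lists.

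The test of whether the sucrose response differed between genotypes asked which genes respond in 1 label and not alike in the other. Pepck1 held 1853 normalized reads in the control library at 0 percent sucrose and 373 ± 14.4 in the 3 control libraries with sucrose (SD, n = 3). In the libraries labelled cabut RNAi it held 1559 ± 69.1 (SD, n = 2) and 1090 ± 191 (SD, n = 6). Its log2 response was -2.31 in controls and -0.54 in the libraries labelled cabut RNAi, a difference of 1.77 ± 0.19 (limma adjusted p = 0.00221). AcCoAS, acetyl-CoA synthetase, went from 507 to 240 ± 13.6 in controls and from 381 ± 20.1 to 561 ± 83.5 in the libraries labelled cabut RNAi (difference 1.62 ± 0.15, adjusted p = 5.84e-04). Thor, which encodes the translation regulator 4E-BP, showed a difference of 1.35 ± 0.19 (adjusted p = 0.0107), with responses of -0.78 in controls and 0.58 in the libraries labelled cabut RNAi.

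**Figure D4:**
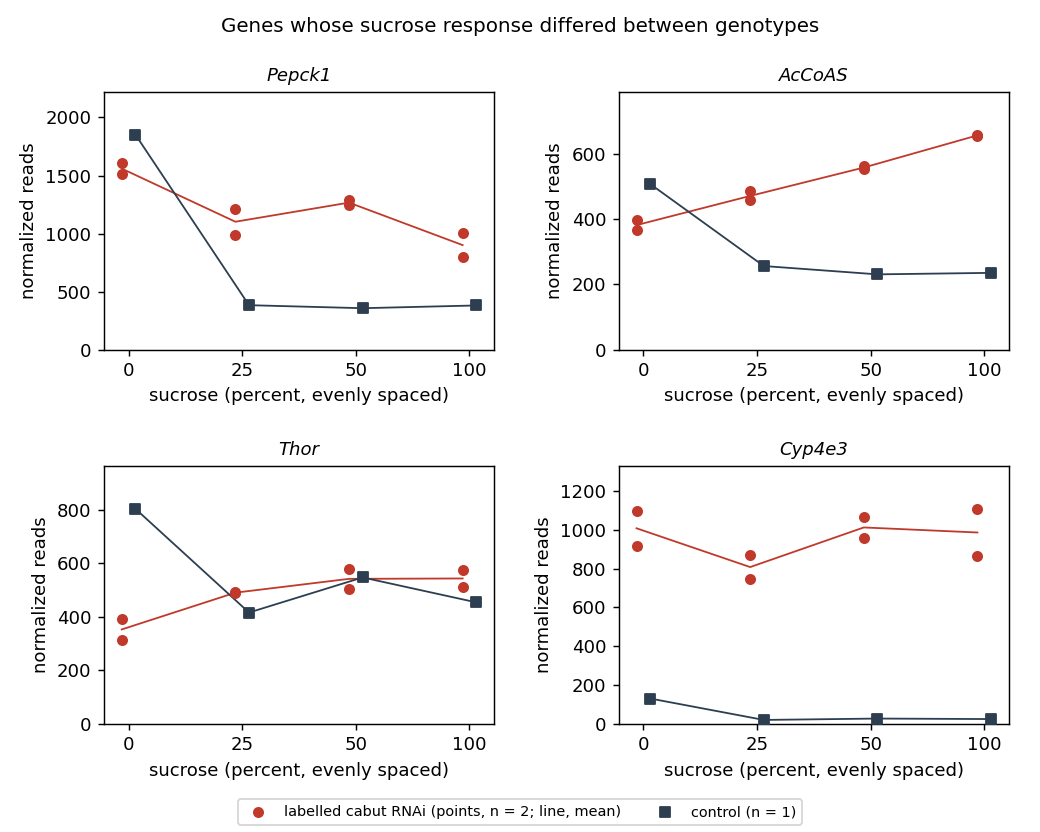
Normalized reads (vertical axis, starting at 0) of Pepck1, AcCoAS, Thor and Cyp4e3 against sucrose concentration (percent, evenly spaced); red points are the 2 libraries labelled cabut RNAi per concentration with a line through their mean, and dark squares are the single control library. Pepck1 lies at 1853 in the control library without sucrose and at 373 ± 14.4 in the 3 control libraries with it (SD, n = 3).

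Cyp4e3 (difference 2.29 ± 0.21), CG10383 (2.06 ± 0.25), Irp-1B (1.56 ± 0.23), CG8654 (1.55 ± 0.22), the threonine dehydrogenase gene Tdh (1.32 ± 0.21), CG3036 (1.12 ± 0.18) and Pepck2 (2.68 ± 0.44) also differed in this direction, and Cyp6a8 in the other (-1.54 ± 0.27). The Pepck2 difference was 1.15 with a pseudocount of 5 (limma adjusted p = 0.314) and 4.87 with edgeR (adjusted p = 0.098). Its call was also lost with quantile normalization (0.0833) and robust limma (0.0653). In all 15 genes passed, 10 with a higher and 5 with a lower response in the libraries labelled cabut RNAi (66.7 percent higher; 85.7 percent of 14 with quantile normalization). Without a filter 95 were higher and 220 lower, and without the trend 4 and 5. The control side of this test rests on 1 library at 0 percent sucrose. In simulated data of the same design 25.6 percent of the limma calls for this comparison were unchanged genes, against 6.3 percent for edgeR. In the real data edgeR called 12 genes, 9 of the 15 among them. Pepck1, AcCoAS, Thor, Cyp4e3, CG10383, Irp-1B, CG8654, Tdh and CG3036 are those 9. DESeq2 called 4, Pepck1, AcCoAS, Thor and Cyp4e3, and not CG10383 (adjusted p = 0.158), Irp-1B (0.191), CG3036 (0.5), CG8654 (0.7) or Tdh (0.979). Leaving out 1 of the 2 libraries labelled cabut RNAi at 0 percent sucrose left 7 or 5 genes, and leaving out the control library at 50 percent gave 23. Of the genes named above, Pepck2 (adjusted p = 0.18 and 0.103), Irp-1B (0.0576 and 0.0964), CG8654 (0.0553 and 0.0894), Tdh (0.119 and 0.0894), CG3036 (0.164 and 0.101) and Cyp6a8 (0.246 and 0.152) were lost in both of the first 2 fits. Thor was lost without the second library (0.0629). Pepck2 (0.0605) and Tdh (0.054) were also lost without the control library at 100 percent. Limma without the trend called 9 genes, and there Pepck1 (0.0985), AcCoAS (0.0622) and Thor (0.183) were not among them. Neither were CG3036 (0.233), CG8654 (0.107), Irp-1B (0.177), Tdh (0.174) and Cyp6a8 (0.177).

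By list, Pepck1 and Pepck2 were the 2 of 7 higher in the sugar sensing list (3 adjusted over the list alone) and the 2 of 15 in the glycolysis list (4 adjusted over the list alone), with camera adjusted p of 1.15e-04 and 7.58e-05. Thor was the 1 of 13 in the FOXO, TOR and starvation list (2 adjusted over the list alone; 1.93e-04), and Cyp6a8 the 1 of 12 in detoxification, downward (3 adjusted over the list alone; 1.15e-04). Without the control library at 100 percent sucrose the sugar sensing and glycolysis lists each had 1 higher. With an estimated correlation the adjusted p was 0.219 for sugar sensing, FOXO and detoxification and 0.287 for glycolysis. No member of another list passed over all genes. Camera called the pentose phosphate (adjusted p = 0.00428), fat body and yolk (0.00455) and ribosomal protein (0.0239) lists upward and mitochondrially encoded genes (0.00278) downward. All were lost with an estimated correlation (adjusted p = 0.287, 0.497, 0.825 and 0.693). Adjusted over the list alone, pentose phosphate had 2 and fat body and yolk 4 higher, the others none. The other 13 lists had camera adjusted p from 0.152 to 0.882, with 1 higher in lipogenesis, 1 higher in circadian and 1 lower in heat shock genes adjusted over the list alone. Median and mean differed in sign for lipogenesis (-0.14 and 0.02), heat shock (0.10 and -0.15), photoreceptor (0.002 and -0.009) and hemocyte (0.02 and -0.12) genes. Among them tim (1.23 ± 0.35, adjusted p = 0.285) and Men, malic enzyme (1.05 ± 0.22, adjusted p = 0.0935), had the smallest p of the circadian and lipogenesis lists.

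Within the libraries labelled cabut RNAi alone, 39 genes rose and 90 fell with sucrose, led by fit (8.01-fold higher, log2 fold change 3.0 ± 0.23), CG3348 and Phyhd1 upward and CG5966 (7.11-fold lower), Shmt (4.73-fold) and GIIIspla2 (4.55-fold) downward. In the controls 28 rose and 48 fell (36.8 percent higher; 25.4 percent of 63 with quantile normalization). The share that rose depended on the setting: edgeR called 2 higher and 47 lower, DESeq2 2 and 31, limma without a filter 287 and 135, and limma without the control library at 100 percent 9 and 33. Named by the rule in controls were GIIIspla2 (5.68-fold), Cyp4e3 (5.30-fold), CG5966 (5.12-fold), Pepck1 (4.96-fold), CG10383 (4.11-fold) and Bcat (4.04-fold) lower and CG3348 (5.18-fold), lolal (2.04-fold) and Pisd (2-fold) higher. The CG3348 value rests on low and uneven control levels. These were 2.56 normalized reads at 0 percent, and 27.7, 4.955 and 35.8 at 25, 50 and 100 percent. The calls of lolal and Pisd were lost without the control library at 25 percent (adjusted p = 0.0976 and 0.0722), and that of Pisd without either library labelled cabut RNAi at 0 percent (0.0527 and 0.0516). These responses come from separate libraries, but both tests took their spread from the same pairs of libraries labelled cabut RNAi. The responses shared 22 genes called lower and 3 called higher. Independent lists would share 0.66 and 0.17. The calls are not independent, so those values are not the overlap expected by chance. In addition 116 of the 129 genes called in the libraries labelled cabut RNAi had the same sign in the controls. Over all genes the correlation of the 2 responses was 0.169, genes not being independent replicates. Without either library labelled cabut RNAi at 0 percent the first count was 40 or 46. Without the control library at 100 percent the second was 42 in place of 76, and Cyp4g1, CG14645 and CG34220, called higher with sucrose in controls, lost the call (adjusted p = 0.17, 0.696 and 0.935). With edgeR the control responses of CG3348 (0.0898), CG14645 (0.0815), CG34220 (0.294), lolal (0.104) and Pisd (0.0772) were not called.

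Among the 9 libraries with sucrose, the trend over 25, 50 and 100 percent (log2 of the percent) passed for 0 genes with limma, with 272 genes at an unadjusted p under 0.05 where chance gives 327. On the recovered reads edgeR called 6 genes and DESeq2 called Men (adjusted p = 0.0287). Limma without the control library at 25 percent called FASN1 and Men (0.0499 each). The 6 of edgeR (CG14645, CG34220, CG34324, CG3906, Muc68D and dhd) were named after their values were seen. Their reads came almost wholly from the control library at 100 percent sucrose, which held 206 reads of CG34324, 73 of Muc68D and 58 of CG3906 against 0 in the other 11, and 63 of dhd against 2. For CG14645 and CG34220 it held 1472.54 and 1233.08 normalized reads, against at most 4.93 and 7.19 in the others. In simulated data with the same trend in both labels, limma recovered 93.9 percent of genes with a 4-fold and 58.2 percent with a 2-fold change from 25 to 100 percent.

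At single concentrations the labels differed in 215 genes at 0 percent sucrose (91 higher and 124 lower in the libraries labelled cabut RNAi, 42.3 percent higher, against 57.7 percent of 168 with quantile normalization). At 25 percent they differed in 135 genes (68 and 67), at 50 percent in 208 (115 and 93) and at 100 percent in 556 (255 and 301). CG3348, Cyp4e3 and Cyp4p1 were higher at all 4 concentrations, with Cyp4e3 7.64-fold at 0 percent and 38.2-, 35.8- and 38.3-fold at 25, 50 and 100 percent. Cyp6a17 was lower at all 4 (at 0 percent, adjusted p = 0.0536 without the first library labelled cabut RNAi), and TotC 12.1-fold lower at 0, 24.5-fold at 25 and 72.8-fold at 100 percent. At 50 percent TotC was not called (log2 fold change -1.72 ± 0.52, adjusted p = 0.112). At 50 percent Gart (3.10-fold) and pug (3.0-fold) were among the lower genes, and at 100 percent CG7299 (6.76-fold) and Akr1B (5.02-fold) among the higher. Across genes the fold changes of separate concentrations had correlations of 0.324 to 0.51, genes not being independent replicates. The control library at 100 percent sucrose held 426 RPM of 16 ovary genes, against at most 6 in the other 11, and 111 RPM of 20 midgut genes, against at most 17.25. The share that was higher depended on the setting. Limma without the trend called 33 higher and 4 lower at 0 percent, 25 and 6 at 25 percent, 40 and 11 at 50 percent and 128 and 85 at 100 percent. With edgeR 57 of 214 genes called at 0 percent were higher, 73 of 198 at 25 percent, 63 of 164 at 50 percent and 63 of 239 at 100 percent. Leaving out 1 of the 2 libraries labelled cabut RNAi of the same concentration gave 76 or 77 genes at 0 percent, as few as 76 at 25 percent, 91 or 124 at 50 percent and 158 or 331 at 100 percent.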

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

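The tests of tissue markers in the control library at 100 percent sucrose were chosen after its values were seen.

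In 15 genes the sucrose response differed between the libraries labelled cabut RNAi and the controls by the test of the difference itself (limma, adjusted p under 0.05). The response was higher on the log2 scale in the libraries labelled cabut RNAi by 2.68 for Pepck2, 2.29 for Cyp4e3, 2.06 for CG10383, 1.77 for Pepck1, 1.62 for AcCoAS, 1.56 for Irp-1B, 1.55 for CG8654, 1.35 for Thor, 1.32 for Tdh and 1.12 for CG3036. It was lower, with differences of -1.54 for Cyp6a8, -2.34 for CG3906, -2.45 for Muc68D, -2.95 for CG34324 and -3.02 for Prestin. Pepck2 has a mean of 14.2 normalized reads and CG3906, Muc68D and Prestin 10.8 to 13.6. With a pseudocount of 5 the Pepck2 difference was 1.15. CG34324, Muc68D and CG3906 had 206, 73 and 58 reads in the control library at 100 percent sucrose and 0 in the other 11, so their fitted values depend on the pseudocount and nothing of them remains without that library. Prestin rests on the control library at 0 percent sucrose, with 1.28 normalized reads against 13.6 ± 4.21 in the 3 controls with sucrose (SD, n = 3). No biological explanation of the 15 was tested beyond the labels, which were not borne out by the level of cbt RNA.

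The control library at 100 percent sucrose held transcripts that were rarer in the others. A list of 16 ovary and early egg genes had 218 reads in it and 56 in the other 11 (426 against 4.2 RPM, reads scaled to a common library total; ratio 101, exact 95 percent interval 75.4 to 139), a list of 20 midgut genes had 57 and 111 (ratio 13.4, 9.55 to 18.6), and the oenocyte gene Cyp4g1 had 492 and 94. These intervals cover counting error and not the spread between libraries, in which the highest of the other 11 held 6 RPM of the ovary list and 17.25 RPM of the midgut list. Low depth would not produce this, since 21 genes had 10 or more reads in it and 2 or fewer in the other 11 together, and neither would a sucrose response shared by both labels, since the libraries labelled cabut RNAi at 100 percent held at most 4.24 RPM of the ovary list. Body tissue as a whole, predicted to raise ovary, midgut and Malpighian tubule lists together, cannot be told apart, because the tubule list (ratio 1.15, lower limit 0.76, upper limit 1.67) is at 49.4 RPM in the other 11, a level that would hide a small share. Tested after that result on the list members not looked at before, ovary tissue remained a candidate source (lower limit of the ratio 10.16; 50.8 RPM against at most 5 in another library). Midgut tissue cannot be told apart from other sources, because the ratio of its remaining members was 3.86 (lower limit 2.13, upper limit 6.56; 31.3 RPM against at most 17.25), and an effect of 100 percent sucrose in control flies alone stays open, with 1 library.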

How the results depend on the processing

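The sum over transcript rows and the list tests without a library were chosen after seeing the data. The cause of each shift was not tested, except that fewer libraries or genes enter where those were left out.

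Counts moved by over 1.5 times as follows (labels 1015, sucrose 141, dose 0, difference of responses 15, response in libraries labelled cabut RNAi 129, in controls 76, labels at 0, 25, 50 and 100 percent sucrose 215, 135, 208 and 556). Limma without the trend gave 59 for sucrose, 9 for the difference, 34 and 31 for the responses, and 37, 31, 51 and 213 for the 4 concentrations. Robust limma gave 151 for the response in controls and 374, 273 and 365 at 0, 25 and 50 percent. Without a filter the difference gave 315 and the responses 81 and 422; with a minimum mean of 50 the response in controls gave 50. On recovered reads edgeR gave 6 for dose, 49 for the response in controls and 239 at 100 percent; DESeq2 gave 1, 33 and 154 for these, 4 for the difference, and 136 and 80 at 0 and 50 percent. The replicate block gave 232 at 25 percent and 342 at 50 percent. The 6 correlations of replicate differences between concentrations were weak, from -0.112 to 0.143. With more calls under the block at these concentrations, whether the numbers pair the libraries stays open.

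Leaving out 1 library gave 723 to 972 genes for labels, 87 to 174 for sucrose, 0 to 2 for dose, 5 to 23 for the difference, 40 to 141 for the response in libraries labelled cabut RNAi and 42 to 108 in controls. At the 4 concentrations it gave 76 to 220, 76 to 139, 91 to 221 and 158 to 558. Lists past the threshold numbered 11 for labels with camera, 0 with an estimated correlation, 6 with fry and 7 without the control library at 100 percent; for sucrose 1 with an estimated correlation and 4 with fry; and for the difference 0 and 2.

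Under the other settings counts stayed within 1.5 times. Over 235 named results, 5063 of 5472 values under alternatives kept direction and side of the threshold, 378 lost and 30 gained the call, and 1 reversed: ATP6 between labels, 0.13 after quantile normalization. With quantile normalization 882 of the 1015 label calls remained and 21 changed sign. Depth limits genes near 10 normalized reads, most in the control library at 100 percent sucrose.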

Other observations

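The tests chosen after the results were seen were those of cbt, of the one-carbon and purine list, of the other groupings of the libraries and of the nearest genes to the ribosomal protein genes. The other tests of ribosomal protein genes and that of chromosome position were chosen before.

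Genes of one-carbon metabolism and purine synthesis, a list of 18 members in the table put together after the sucrose result was seen, fell with sucrose and were also lower in the libraries labelled cabut RNAi. Of 17 tested, 12 were lower with sucrose and none higher (median log2 fold change -0.91). Among all genes 1.48 percent were lower. Leaving aside the 5 already named for sucrose, 7 of 12 were lower, among them Nmdmc (-2.18 ± 0.27), Adsl (-1.38 ± 0.17), Prps (-0.91 ± 0.12), pug (-0.81 ± 0.18) and Paics (-0.77 ± 0.11). Of these, pug had been named between labels at 50 percent sucrose. Between labels 11 of the 17 were lower and none higher (median -0.49), against 8.72 percent of all genes lower. Values were Nmdmc at -1.59 ± 0.24, Gart at -1.40 ± 0.14, pug at -1.34 ± 0.16 and Paics at -1.11 ± 0.10. Ts and bur had log2 fold changes with sucrose of 0.09 ± 0.17 and -0.07 ± 0.18.

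The lower ribosomal protein genes in the libraries labelled cabut RNAi (79 of 82, median -0.54) were set against 3 technical explanations. Scaling that acts on abundant genes alike cannot be told apart: 90 other genes matched on mean value had a median of -0.17 (bootstrap 95 percent interval -0.24 to -0.04), above the halved ribosomal median of -0.27, but their median value was 1556 against 2745 normalized reads. With the nearest other gene for each ribosomal protein gene (40 genes, median value 2656), a test chosen after that result, the median was -0.24 and its interval, -0.44 to -0.15, reached the bound. For 82 genes matched on transcript length and mean value the median was -0.18, but its interval, -0.28 to -0.02, reached that bound, so a bias of short transcripts cannot be told apart. A difference in the distribution of values between libraries remains a candidate explanation, because quantile normalization moved the median to -0.107. That scaling forces the highest ranks of all libraries to equal values, and these genes hold many of those ranks. The genotype difference of the labels stays open and was not tested apart from these.

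That cbt RNA was not lower in the libraries labelled cabut RNAi was weighed against 3 explanations. An exchange of labels between some libraries of the 2 genotypes is argued against by the first principal component of all 6549 tested genes, found without the labels, on which 0 libraries lay inside the range of the other label (-16.2 to -6.70 for cabut RNAi, 18.7 to 33.4 for controls). An exchange of every label stays open. The w values, 24.4 to 42.4 normalized reads in the libraries labelled cabut RNAi and 4.96 to 15.9 in the controls, go with the labels if driver and UAS transgenes both carry a white marker, which the labels do not state. The choice of transcript row is argued against by the other cbt row, whose log2 difference was 0.382. Hairpin RNA counted as cbt cannot be told apart (log2 fold change 0.383), since the reads were not available to separate the transgene from the gene. A knockdown limited to cells that express timeless, diluted in whole heads, is a further hypothesis that was not tested.

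A hypothesis for the large differences between labels is that linked stretches of another stock's chromosomes surround the transgenes. Genes called between labels were adjacent in 184 pairs, where 10000 random placements gave 137.9 on average (95 percent of them 119 to 158; permutation p = 0.0001, the smallest the placements can give). For calls of at least 2-fold there were 24 pairs against 4.0 expected (ratio 5.97, 95 percent of placements 1 to 8, permutation p = 0.0001). The sucrose calls had 5 pairs against 2.8 expected, inside the range of random placements (0 to 6; permutation p = 0.142). Their ratio of 1.82, against 1.33 for all label calls, rests on few pairs, so whether all label calls cluster more than sucrose calls was not decided. The label calls of at least 2-fold did lie side by side more often than random placement gives, but the hypothesis stays open. Related genes that lie side by side and share regulation may give the same pattern. Of tested genes on 2L and 2R 17.6 and 19.5 percent were called between labels, and on 3L, 3R and X 13.5, 14.2 and 12.3 percent. For calls of at least 2-fold the shares were 3.73 and 3.43 percent on 2L and 2R, and 2.29, 2.26 and 0.89 percent on 3L, 3R and X.

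Other groupings of the libraries were compared with the real ones. Of the 81 ways to choose 1 library per concentration as control, 1, the real one, called as many genes as the 1015 found between labels, and the highest other called 3; this is under the 5 percent of groupings set as the limit for chance. Of 100 groupings of the libraries for sucrose, 1 called as many as the real 141, and the highest other called 6. In both comparisons every other grouping mixed the real groups, which adds their difference to the spread and lowers the calls. The counts of 3 and 6 are therefore not those of libraries without a difference, and 1 of 81 is the smallest share the first comparison can give. For dose the real count was 0, which any of the 100 groupings reaches whatever the data, so this comparison says nothing about chance; the highest other called 5.

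Cuticle-related Acp1 ranged widely among libraries labelled cabut RNAi, with 20.2 ± 21 normalized reads at 0 percent sucrose (SD, n = 2) and 486 ± 468 with sucrose (SD, n = 6), against 9.69 ± 2.93 in the 4 controls (SD, n = 4). The 2 libraries of 1 concentration could differ as widely. They held 8.49 and 1273 at 25 percent, 146 and 783 at 50 percent, and 421 and 286 at 100 percent.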
